A study of Mus musculus with 28 samples.

How the data were processed

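The series holds 28 samples of bone marrow-derived macrophages, per the labels: 15 GR libraries (4 vehicle, 4 Cort, 4 Dex and 3 IL4), 12 H3K27ac libraries (3 per group) and 1 H3K27ac input library, which has no column in the deposited tables and was not analysed here. Chromatin was crosslinked with disuccinimidyl glutamate and formaldehyde for GR and with formaldehyde for H3K27ac, per the labels. Replicate numbers and, for GR, the batch were taken from the sample titles. The columns headed C were matched to the vehicle libraries by elimination, since every other column names its treatment.

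The deposited values are raw read counts per peak, over a peak set common to all libraries of an assay, and the authors made them with fastp, Bowtie2, SAMtools, MACS2 and featureCounts on mm10, per the submitters' processing notes, which give no versions. How peaks were merged, and whether duplicates or excluded regions were removed, is not stated. Both tables have a column named filtered whose criterion is not stated. It is TRUE for 2296 of 8394 GR peaks and 33835 of 63313 H3K27ac peaks, and all peaks were used except in an alternative. The median peak length was 114 bp for GR and 1013 bp for H3K27ac. All per-sample columns held whole numbers and were matched to a sample.

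Counts were compared in R 4.3.3 with edgeR 4.0.16. Peaks with low counts were removed by filterByExpr by group, TMM factors were computed from counts in peaks, and quasi-likelihood F tests were made in a fit of all libraries of the assay, with batch as a covariate for GR. Peaks were called at a Benjamini-Hochberg adjusted p under 0.05, over all tested peaks. The standard error is the absolute log2 fold change divided by the square root of F. Since scaling used counts in peaks, changes are relative to the other peaks. IL4 GR libraries are in batch 2 alone, so their comparison rests on batch 2 and the batch difference of the other groups. DESeq2 1.42.0 (Wald test, same design) was run beside it. Samples, comparisons, lists and the rule for named peaks were chosen before the data were examined. So were the tests, other than those named in the text as chosen later and those of patterns found in the GR counts.

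Peaks were assigned to the gene whose span lay nearest, within 50 kb, among 20014 named genes of the 49997 in a RefSeq table for mm10. The table gives no strand, so distance to the gene span replaced distance to the transcription start, and peaks within 1 kb of either gene end replaced promoter peaks. By this rule 80.2% of GR peaks and 89.5% of H3K27ac peaks had a gene, 50.9% and 65.8% lay in a gene and 9.7% and 18.8% within 1 kb of a gene end. A genome sequence was not used here, so a test of GR and STAT6 motifs was not run. For each treatment against vehicle the text takes its names from the 10 largest and 10 lowest log2 fold changes (5 between treatments) among called peaks with at least the median abundance and every treated library beyond every vehicle library, within batch for GR, at most 1 peak per gene, leaving out predicted genes. For each list it names up to 4 of the genes with the smallest p, each by its peak with the smallest p, whether or not it passed.

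The 12 gene lists (glucocorticoid-induced, IL4/STAT6-induced, inflammatory, interferon-response, MHC class II, circadian, phagocytosis and scavenger receptor, lipid metabolism, tissue remodelling, macrophage identity, housekeeping, and STAT, KLF and bZIP regulators) and 7 lists of markers of other cell types (fibroblast, neutrophil, lymphoid, dendritic, mast or basophil, erythroid or megakaryocyte, and osteoclast) were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, where a list had at least 5 peaks. Macrophages also express several osteoclast and dendritic markers, and a peak near a gene is no measure of its transcript. H3K27ac and GR peaks were overlapped by at least 1 bp with bedtools 2.31.1 and compared with Fisher's exact test, two-sided, across peaks. Shared calls were set beside the product of the list sizes over the number of tested peaks and beside 10 simulations of unchanged groups against the same vehicle libraries.

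The alternatives chosen beforehand were median-of-ratios and total-count scaling, scaling by the 25% of peaks with the lowest counts, no count filter, DESeq2, an absolute log2 fold change of at least 1, fits of the compared groups alone, a replicate block, no batch term, each batch alone, other overlap and gene distances, and leaving out each library. Chosen after the data were seen were leaving out Cort replicate 4 of GR, with and without total-count scaling or batch 2 alone, leaving out the 1% of GR peaks with the most reads, and using peaks with filtered TRUE. Residual correlations of H3K27ac libraries were 0.268 to 0.678 in 18 pairs with the same number and -0.449 to 0.0406 in the others, and the libraries were taken as paired. The main fit was fixed beforehand without this pairing. Its H3K27ac calls, standard errors and p-values therefore ignore the pairing, and counts with the replicate block are given beside them. For GR they were -0.463 to 0.176 in 21 pairs and -0.547 to 0.561 in the others, and the libraries were not taken as paired. Some of these 21 pairs join IL4 libraries of batch 2 with libraries of batch 1, which cannot be true pairs. The lowest value is that of vehicle replicate 4 with Cort replicate 4.

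The pipeline was tested on simulated data with 200 peaks changed in a Dex against vehicle comparison. At 1.5, 2 and 4-fold edgeR recovered 0%, 11.9% and 51.5% of changed H3K27ac peaks (3 calls among unchanged peaks) and 0%, 0% and 22.7% of changed GR peaks. DESeq2 recovered 5.97%, 29.9% and 65.2% (31 calls among unchanged peaks) and 0%, 1.49% and 39.4%. No recovered peak had the wrong direction. A list of raised peaks had a camera p of 3.89e-149 for H3K27ac and 2.51e-54 for GR by limma, and a random list 0.713 and 0.933. The pass mark was changed after this result was seen. It had asked for at least 70% recovery at 4-fold for H3K27ac. The later mark asked for few wrong directions, 4-fold estimates near their true size and the right camera result for both lists. It set no limit on false calls. With so few changed peaks, small changes were mostly missed in the simulation, above all in GR. Most comparisons with vehicle in the data called more peaks, which loosens the cutoff on p. The simulated shares therefore do not carry over to them directly, though small changes may still be missed. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Among the H3K27ac peaks that fell with a steroid, 2 that met the rule for named peaks are not reported here.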

Results

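Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out on macrophages grown from the bone marrow of male C57BL/6 mice aged 8 to 10 weeks and differentiated for 5 days in L-cell conditioned medium. The cells received vehicle, corticosterone (Cort, the natural glucocorticoid of mice) at 500 nM, dexamethasone (Dex, a synthetic glucocorticoid) at 100 nM, or interleukin 4 (IL4, a cytokine that drives alternative macrophage activation through STAT6) at 10 ng/ml, with 24 h of treatment. The titles of the H3K27ac vehicle libraries state no time. Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active enhancers and promoters, was measured in 12 libraries with 3 per group. The glucocorticoid receptor (GR), the nuclear receptor that binds both steroids, was measured in 15 libraries, 4 each for vehicle, Cort and Dex and 3 for IL4. The GR libraries came in batches 1 and 2, and the IL4 libraries were all in batch 2. H3K27ac counts in peaks ranged from 6829787 to 15695771 per library over 63313 peaks, of which 59881 had enough reads to test. GR counts in peaks ranged from 900063 to 1981582 over 8394 peaks, of which 5183 were tested. A single region at 2:98666249-98667322 held 45.4% to 59.2% of each GR library's counts, and the 1% of peaks with the most reads held 77.5% to 96.1%, so that 56214 to 416169 counts per library lay in all other GR peaks. The biological coefficient of variation was 0.24 for H3K27ac and 0.439 for GR. Coordinates are of mouse build mm10, and peaks are named by the nearest gene within 50 kb unless a distance is given. Changes are log2 fold changes ± standard error from edgeR's quasi-likelihood fit, with Benjamini-Hochberg adjusted p over all tested peaks, and a peak is called higher or lower where the adjusted p lies under 0.05. The libraries were not stated to come from separate animals, so the p-values cover only the spread between libraries.

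Corticosterone was compared with vehicle to ask where the physiological hormone altered H3K27ac. The genes named first are those of the glucocorticoid-induced list, chosen before the data were examined, with the smallest p. The peak near Cd163 (6:124277633-124281022), the haemoglobin scavenger receptor, went from 8.58 ± 1.43 to 82.4 ± 10.0 TMM-normalised CPM (counts scaled to a library size in common) (SD, n = 3 each), a log2 change of 3.27 ± 0.18 (adjusted p = 4.53e-06). The peak near Tsc22d3 (X:140503569-140515614), which encodes the glucocorticoid-induced leucine zipper, rose by 2.29 ± 0.14 (adjusted p = 6.23e-06). The peak near Klf9 (19:23132836-23136994), a zinc finger repressor, rose by 3.84 ± 0.26 (adjusted p = 1.43e-05), and the peak in Fkbp5 (17:28417181-28423716), a co-chaperone of GR, by 2.33 ± 0.21 (adjusted p = 6.54e-05). In all, 704 peaks were higher and 225 lower with Cort. By the rule for named peaks, the rises with the highest fold were at an intergenic site 60.2 kb from Trpm3 and 82.4 kb from Klf9 (19:23055641-23058868, 4.73 ± 0.41), near Armc12 (17:28521675-28526085, 4.54 ± 0.32) and in Zbtb16 (9:48722671-48725109, 4.01 ± 0.53). The Armc12 peak also lies within 50 kb of Fkbp5. Next came sites 123 kb from Sv2b (7:74988387-74991848, 3.96 ± 0.29), and between Anapc16 and the stress gene Ddit4 (10:59969317-59971359, 3.92 ± 0.35). Falls were smaller. They included peaks in Fat3 (9:16317775-16319883, -1.70 ± 0.32), Megf10 (18:57166587-57168449, -1.62 ± 0.29), Plxna2 (1:194755616-194757488, -1.53 ± 0.22), Blnk (19:40976903-40983120, -1.51 ± 0.26) and Camsap3 (8:3593771-3596165, -1.43 ± 0.22). All 3 Cort libraries lay beyond all 3 vehicle libraries in the stated direction at the peaks named for their fold, which the rule required.

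Of the 29 measured genes of the glucocorticoid-induced list, 10 had peaks that rose with Cort, 0 had peaks that fell and 19 did not pass. Of its 196 peaks 51 were higher and 0 lower, or 74 and 1 adjusted over the list alone (camera adjusted p = 3.15e-34, and adjusted p = 0.00117 with an estimated correlation). Among 23 STAT, KLF and bZIP regulators, Klf9, Klf13 (7:63894363-63900930, 2.74 ± 0.19) and Fos (12:85522225-85525505, 2.05 ± 0.16) rose and 20 did not pass. That list had 11 higher and 0 lower peaks, or 14 and 1 adjusted over the list alone (adjusted p = 7.7e-05, and adjusted p = 0.036 with an estimated correlation). It shares Cebpd, Klf2, Klf4 and Klf9 with the glucocorticoid-induced list, which also holds Per1 of the circadian list. Of 23 phagocytosis and scavenger receptor genes, Cd163, Mertk (2:128743557-128754460, 1.30 ± 0.12), a receptor for apoptotic cells, Fcgr3 (1:171049649-171060877, 0.80 ± 0.14) and Stab1 (14:31157183-31176699, 0.60 ± 0.11) rose and 1 fell. Cd163 and Mertk also belong to the glucocorticoid-induced list. The 15 higher and 1 lower peaks of the list, or 23 and 4 adjusted over the list alone, gave adjusted p = 0.000602, and adjusted p = 0.0835 with an estimated correlation. Among 15 circadian genes Per1 (11:69095029-69101124, 1.23 ± 0.13), Per2 (1:91435879-91438725, 1.65 ± 0.33) and Nfil3 (13:52984534-52986720, 1.41 ± 0.18) rose, while the list's median of -0.0291 and mean of -0.0127 differed in sign from its test, which pointed up (adjusted p = 0.616). Of 33 IL4/STAT6-induced genes 5 rose and 0 fell, including Slc7a2 (8:40850641-40852344, 1.93 ± 0.37), Atp6v0d2 (4:19878948-19881494, 1.11 ± 0.20), Kdm6b (11:69417438-69420365, 0.95 ± 0.17) and Il4ra (7:125558178-125562173, 0.84 ± 0.16). The list had 5 higher and 0 lower peaks, or 8 and 2 adjusted over the list alone (adjusted p = 0.499). The lipoprotein lipase gene Lpl fell (8:68905560-68917015, -0.93 ± 0.16), and Apoe (7:19692487-19702460, 0.89 ± 0.17) and Fabp4 (3:10205119-10209584, 0.94 ± 0.21) rose, among 21 lipid metabolism genes (adjusted p = 0.67). F13a1 (13:37055415-37058175), the factor XIII A subunit, rose by 1.82 ± 0.22 as the only called gene of 17 in tissue remodelling (adjusted p = 0.697). Ccl3 (11:83630235-83632471, 15.4 kb away) rose by 0.81 ± 0.16 as the only called gene of 23 in the inflammatory list (adjusted p = 0.616). In the interferon-response list Ifih1 fell (2:62634645-62636323, -1.17 ± 0.24) as 1 of 18, and its median of 0.0966 and mean of 0.0671 lay above 0 while its test pointed down (adjusted p = 0.657). None of 12 MHC class II, 17 macrophage identity or 11 housekeeping genes passed (adjusted p = 0.962, 0.616 and 0.616). Among markers of other cell types, Flt3 (5:147392209-147393948, 2.96 ± 0.36), a dendritic cell progenitor receptor, and Pdgfrb (18:61085887-61087958, 0.88 ± 0.17), a mesenchymal receptor, rose, and no peak of the neutrophil, lymphoid, mast or basophil, erythroid or megakaryocyte, or osteoclast markers passed. The lymphoid markers' 5 peaks tested down with the replicate number as a block (adjusted p = 0.0388) and not without it (adjusted p = 0.123).

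Replicate numbers paired the H3K27ac libraries, which the fit used above ignores. With the number as a block 3858 peaks were higher and 3673 lower with Cort. The block also changed the calls in the lists above: glucocorticoid-induced genes had 77 higher and 6 lower, regulators 27 and 6, phagocytosis genes 36 and 12, IL4/STAT6-induced genes 21 and 14, circadian genes 7 and 3, lipid metabolism genes 14 and 15, tissue remodelling genes 8 and 11, macrophage identity genes 14 and 3, inflammatory genes 13 and 4, interferon-response genes 1 and 4, housekeeping genes 0 and 1, neutrophil markers 4 and 0, lymphoid markers 0 and 2, dendritic markers 4 and 3 and osteoclast markers 1 and 2. The share of higher among called peaks was 75.8%, against 90.8% with scaling by low-count peaks (670 higher, 68 lower) and 63.2% with scaling by total count (557 higher, 324 lower). The count of 929 fell to 403 without vehicle replicate 2, 328 without vehicle replicate 3, 438 without Cort replicate 1 and 474 without Cort replicate 3. The lower calls alone fell from 225 to 80, 28, 45 and 42 in the same order, and the higher calls from 704 to 323, 300, 393 and 432. Without vehicle replicate 1 the higher calls fell to 461, and without Cort replicate 2 the lower calls rose to 351.

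Dexamethasone changed H3K27ac at 1734 higher and 1404 lower peaks. Of the same list, the Cd163 peak rose by 3.32 ± 0.18 (adjusted p = 3.85e-06), the Tsc22d3 peak by 2.37 ± 0.14 (adjusted p = 4.11e-06), the Klf9 peak by 4.01 ± 0.26 (adjusted p = 5.06e-06) and a peak in Fkbp5 (17:28482632-28486108) by 3.08 ± 0.25 (adjusted p = 1.94e-05). The site between Trpm3 and Klf9 rose by 5.26 ± 0.42, the Armc12 peak by 4.72 ± 0.32, the peak between Anapc16 and Ddit4 by 4.54 ± 0.35, the Zbtb16 peak by 4.28 ± 0.53, a peak in Mctp2 (7:72161397-72164061) by 4.12 ± 0.54 and a peak in Ppp1r21 (17:88579636-88583761) by 4.03 ± 0.26. Falls by the rule included peaks near Sptbn1 (11:30081208-30084348, -2.34 ± 0.48) and in Btbd11 (10:85654811-85656696, -2.34 ± 0.45), Cks1brt (8:85159717-85161205, -2.29 ± 0.43) and Myl4 (11:104581815-104583388, -2.15 ± 0.42). All 3 Dex libraries lay beyond all 3 vehicle libraries at the peaks named for their fold, again by the rule.

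The glucocorticoid-induced list had 13 genes that rose, 3 that fell and 13 that did not pass, with 67 higher and 3 lower peaks, or 89 and 10 adjusted over the list alone (adjusted p = 2.7e-31, and adjusted p = 0.00155 with an estimated correlation). Of the regulators Klf9, Klf13 (2.90 ± 0.19), Fos (2.13 ± 0.16) and Fosl2 (5:32133085-32140406, 0.47 ± 0.12) rose and 1 fell, with 18 and 1 peaks, or 22 and 2 adjusted over the list alone (adjusted p = 0.00025, and adjusted p = 0.0463 with an estimated correlation). Of the phagocytosis genes 8 rose and 2 fell, among them Mertk (1.29 ± 0.12), Fcgr3 (0.86 ± 0.14) and Stab1 (0.61 ± 0.11), with 24 and 3 peaks, or 28 and 4 adjusted over the list alone (adjusted p = 0.00066, and adjusted p = 0.0923 with an estimated correlation). Per1 (1.35 ± 0.13), Per2 (2.38 ± 0.33) and Nfil3 (1.66 ± 0.18) rose again, with a circadian median of -0.0817 and mean of -0.0308 against a test pointing up (adjusted p = 0.557). Of the IL4/STAT6-induced genes 11 rose and 4 fell, with rises at Chil3 (3:106170194-106171454, 2.76 ± 0.43), a marker of alternative activation, Atp6v0d2 (1.20 ± 0.20), Kdm6b (1.17 ± 0.17) and Il4ra (1.01 ± 0.16). Their 12 higher and 5 lower peaks, or 13 and 7 adjusted over the list alone, did not shift as a list (adjusted p = 0.546). In tissue remodelling F13a1 (2.04 ± 0.22) and 1 other gene rose and 6 fell, including Pdgfb (15:80029960-80031701, -0.78 ± 0.15), Tgfb1 (7:25700392-25701249, -1.07 ± 0.26) and Tgfbi (13:56623844-56624534, -1.13 ± 0.28), and the list did not pass (adjusted p = 0.546). Lpl (-1.24 ± 0.16) and a Pparg peak (6:115332860-115335519, 25.4 kb away, -0.83 ± 0.19) fell, Fabp4 (1.13 ± 0.21) and Apoe (0.92 ± 0.17) rose, and 16 of 21 lipid metabolism genes did not pass (adjusted p = 0.546). Among inflammatory genes Ccl3 (0.81 ± 0.16) and Nlrp3 (11:59559348-59560301, 0.99 ± 0.25) rose and Cd40 (2:165060327-165062446, -0.85 ± 0.21) fell, and in the interferon list Ifih1 fell (-1.21 ± 0.24), with a median of 0.102 and a mean of 0.055 against a test pointing down (adjusted p = 0.546 for both lists). Irf8 (8:120792316-120793729, 35.6 kb away) rose by 0.94 ± 0.21 as 1 of 17 macrophage identity genes, and no MHC class II or housekeeping gene passed (adjusted p = 0.546, 0.831 and 0.546).

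Of the markers of other cells, Flt3 (3.48 ± 0.36), Siglech (7:55783629-55785875, 0.70 ± 0.18), Pdgfrb (0.93 ± 0.17) and Oscar (7:3597481-3598905, 1.40 ± 0.30) rose with Dex, and Nfatc1 (18:80656186-80656946, -1.30 ± 0.31) fell. The B-cell gene Ms4a1 fell (19:11266113-11267730, -1.16 ± 0.25), and the 5 peaks of the lymphoid markers tested down (adjusted p = 0.0327, and adjusted p = 0.344 with an estimated correlation). The dendritic markers had a median of -0.249 and a mean of 0.0988, with a test pointing up (adjusted p = 0.546). With the block 5937 peaks were higher and 6194 lower, with 94 and 16 in the glucocorticoid-induced list, 34 and 11 in regulators, 50 and 17 in phagocytosis, 26 and 21 in IL4/STAT6-induced, 12 and 9 in circadian, 19 and 29 in lipid metabolism, 10 and 17 in tissue remodelling, 14 and 9 in macrophage identity, 16 and 6 in inflammatory, 4 and 4 in interferon-response, 4 and 3 in MHC class II and 1 and 1 in housekeeping genes. Neutrophil markers had 5 and 0, dendritic 4 and 4, osteoclast 1 and 4 and mast or basophil 0 and 1. Higher peaks made up 55.3% of calls, against 45.0% with scaling by total count (1467 higher, 1793 lower) and 64.5% with scaling by low-count peaks (1473 higher, 810 lower). The count of 3138 fell to 1578 without vehicle replicate 2, 1185 without vehicle replicate 3, 1402 without Dex replicate 1 and 1386 without Dex replicate 3 (higher 868, 804, 950 and 953, lower 710, 381, 452 and 433), and |log2 change| of at least 1 left 1979.

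**Figure D1:**
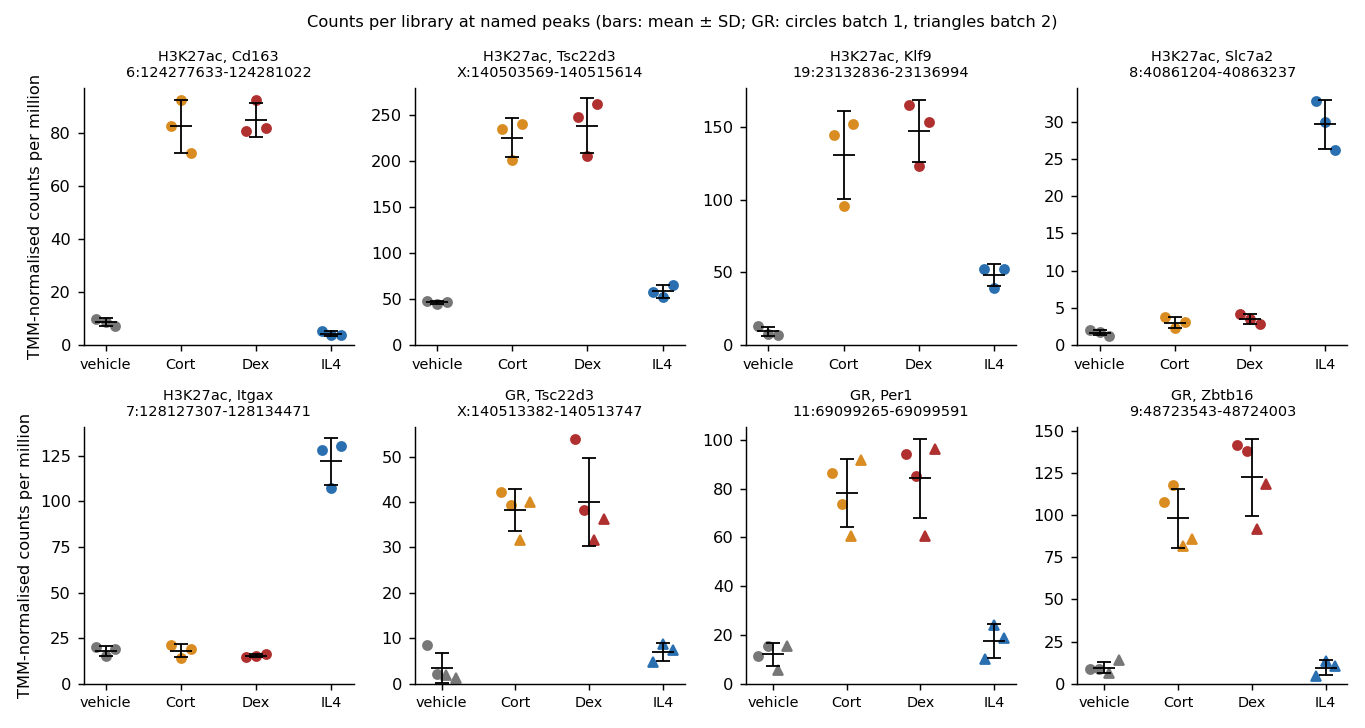
TMM-normalised CPM of each library at 5 H3K27ac and 3 GR peaks, by treatment, with the mean and SD of each group as bars (H3K27ac n = 3, GR n = 4, IL4 in GR n = 3; GR circles are batch 1 and triangles batch 2). Cd163 H3K27ac lay between 72.3 and 92.4 in the Cort and Dex libraries and at or below 9.91 in the vehicle and IL4 libraries, while Slc7a2 and Itgax H3K27ac stood out in IL4.

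The steroids were compared directly, at doses that differed (500 nM Cort and 100 nM Dex). Corticosterone and dexamethasone are related steroids, of which dexamethasone carries a fluorine and a methyl group that corticosterone lacks. At Cd163 the log2 changes were 3.27 ± 0.18 with Cort and 3.32 ± 0.18 with Dex, at Klf13 2.74 ± 0.19 and 2.90 ± 0.19, at Per2 1.65 ± 0.33 and 2.38 ± 0.33, at Flt3 2.96 ± 0.36 and 3.48 ± 0.36, and at Lpl -0.93 ± 0.16 and -1.24 ± 0.16. No H3K27ac peak differed between Dex and Cort in edgeR's test (0 of 59881, 793 at an unadjusted p under 0.05, 0 in DESeq2), and none did with the replicate block. Over the 3153 peaks called with either steroid, the Dex change was larger in size at 94.4%, the slope of Dex on Cort was 1.24, and the 95% interval of the difference lay within 1 log2 unit at 71.8%. Over all 59881 tested peaks these values were 61.3%, 0.991 and 60.7%. Over the 914 peaks called with both, the slope was 1.15 and 82.7% of intervals lay within that bound. Selection by a call and the shared vehicle libraries enter these slopes.

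IL4 changed H3K27ac at 8827 higher and 7711 lower peaks. Of the IL4/STAT6-induced list, the genes with the smallest p were Matk (10:81255576-81258598), which rose by 3.91 ± 0.20 (adjusted p = 5.34e-07), the arginine transporter Slc7a2 (8:40861204-40863237) by 4.20 ± 0.25 (adjusted p = 8.55e-07), Itgax (7:128127307-128134471), which encodes CD11c, by 2.75 ± 0.17 (adjusted p = 9.83e-07) and Rnase2a (14:51236876-51239499, 15.8 kb away) by 2.95 ± 0.20 (adjusted p = 1.52e-06). Slc7a2 went from 1.65 ± 0.376 to 29.7 ± 3.27 and Itgax from 18.2 ± 2.80 to 122 ± 12.7 normalised CPM (SD, n = 3 each). The highest folds by the rule were near Ang5 (14:43952259-43954184, 5.43 ± 0.36) and Ear10 (14:43938325-43940695, 5.23 ± 0.52), in a cluster of near-identical ribonuclease genes where reads cannot be assigned with certainty, and in Tex9 (9:72485610-72486624, 5.05 ± 0.51). Others lay near Klhl25 (7:75904309-75906351, 4.70 ± 0.41), in Il31ra (13:112550914-112553062, 4.62 ± 0.33), in Mad1l1 (5:140147983-140152228, 4.54 ± 0.33) and near Gpr65 (12:98310006-98313689, 4.53 ± 0.29). Falls were found near the integrin gene Itgal (7:127292042-127294533, -3.56 ± 0.48), in Adgrg6 (10:14516433-14518531, -3.52 ± 0.58), near Oprd1 (4:132096520-132097932, -3.46 ± 0.39), in Svil (18:5084221-5086750, -3.38 ± 0.68) and 48.8 kb from Ifng (10:118494690-118496413, -3.34 ± 0.48). The rule again required all 3 IL4 libraries to lie beyond all 3 vehicle libraries at the peaks named for their fold.

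Of 33 measured IL4/STAT6-induced genes, 23 had peaks that rose, 1 fell, 6 had both and 3 did not pass. The list had 111 higher and 10 lower of 234 peaks, or 130 and 15 adjusted over the list alone (adjusted p = 1.06e-17, and adjusted p = 0.0276 with an estimated correlation). MHC class II genes followed, with 8 of 12 higher and 1 lower, including the transactivator Ciita (16:10486470-10490675, 2.42 ± 0.30), H2-Aa (17:34286489-34287856, 1.93 ± 0.23) and H2-DMa (17:34135541-34136894, 1.52 ± 0.22). The invariant chain gene Cd74 also rose. Their 20 higher and 1 lower peaks, the same numbers adjusted over the list alone, gave adjusted p = 0.00624, and adjusted p = 0.178 with an estimated correlation. Of 21 lipid metabolism genes 11 rose, 2 fell and 3 had both, with Pparg (6:115348292-115351199, 2.57 ± 0.31), Fabp4 (3:10212744-10214270, 2.21 ± 0.29), Abcg1 (17:31065745-31068261, 1.96 ± 0.27) and Lpl (8:68917370-68921217, 1.30 ± 0.18) among the rises (41 and 8 peaks, 41 and 7 adjusted over the list alone, adjusted p = 0.00624, and adjusted p = 0.178 with an estimated correlation). Of 15 circadian genes 4 rose, 4 fell and 1 had both. Bhlhe40 (6:108708425-108710502, 3.13 ± 0.23) and Npas2 (1:39291964-39294320, 2.24 ± 0.34) rose and Arntl (7:113194613-113198478, -0.93 ± 0.15) fell (27 and 12 peaks, 28 and 15 adjusted over the list alone, adjusted p = 0.024, and adjusted p = 0.178 with an estimated correlation). The glucocorticoid-induced genes went both ways, with 7 higher, 11 lower and 1 with both of 29. Klf9 (2.39 ± 0.25) and Klf4 (4:55574852-55576351, 42.4 kb away, 2.62 ± 0.30) rose and Irak3 (10:120162359-120166996, -1.17 ± 0.11) and Cebpd (16:15886279-15892560, -0.99 ± 0.11) fell (17 and 29 peaks, 16 and 28 adjusted over the list alone, adjusted p = 0.226).

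The remaining lists did not pass with IL4. Among 23 phagocytosis genes 9 rose, 5 fell and 1 had both (adjusted p = 0.226), with Fcgr3 (1:171046160-171049074, 1.97 ± 0.21) and the inhibitory receptor Fcgr2b (1:170959600-170964999, 1.89 ± 0.14) rising and the scavenger receptor Marco falling (1:120501536-120506129, -2.46 ± 0.32). Among 17 tissue remodelling genes 9 rose, 4 fell and 2 had both (adjusted p = 0.0705), including Mmp12 (9:7342914-7349553, 2.02 ± 0.28), Hbegf (18:36511816-36513302, 1.88 ± 0.20) and Tgfbi (13:56630825-56635363, -1.36 ± 0.19). Inflammatory genes split 5 higher, 5 lower and 2 with both of 23 (adjusted p = 0.314), with Ccl3 at 1.00 ± 0.16 and Nfkb1 (3:135616243-135617684) at -1.52 ± 0.25. Interferon genes split 2, 4 and 2 of 18 (adjusted p = 0.5), with Irf1 (11:53817807-53819379, 39.4 kb away) at 2.97 ± 0.25 and Ifih1 at -1.93 ± 0.25. Macrophage identity genes split 5, 4 and 6 of 17 (adjusted p = 0.192), with rises at Tlr4 (4:66855911-66859117, 1.48 ± 0.14) and Runx1 (16:92851336-92854421, 2.17 ± 0.23). Regulators split 8, 3 and 10 of 23 (adjusted p = 0.0867), with Batf3 (1:191092428-191094924) at 2.61 ± 0.20. Of 11 housekeeping genes 3 rose and 1 fell (adjusted p = 0.926). Among markers of other cells, the dendritic genes Xcr1 (9:123857907-123859798, -2.44 ± 0.55), Siglech (-1.12 ± 0.19) and Flt3 (5:147362386-147363899, -1.05 ± 0.35) fell and Zbtb46 (2:181409879-181411232, 1.37 ± 0.33) rose. That list was called down with the block (adjusted p = 0.00817) and not without it (adjusted p = 0.0775). Of 6 osteoclast genes 4 rose, including Ctsk (3:95493043-95507506, 1.01 ± 0.20), 1 fell and 1 had both, and their median of 0.0689 and mean of -0.00833 differed in sign (adjusted p = 0.821, test pointing up). Cxcr2 (1:74154919-74155690, 2.92 ± 0.35) rose and Mmp8 (9:7553352-7554892, -1.08 ± 0.25) and Ltf (9:111045801-111047085, -0.58 ± 0.20) fell among neutrophil markers (adjusted p = 0.821). Pdgfrb rose (1.18 ± 0.17), Ms4a1 (19:11260713-11265178, -1.08 ± 0.22) and Pf4 (5:90770385-90773738, -0.94 ± 0.19) fell, and no mast or basophil marker passed. With the block 13134 peaks were higher and 12923 lower, with 20 and 9 in MHC class II, 21 and 35 in inflammatory, 10 and 16 in interferon-response and 5 and 7 in housekeeping genes. The block also gave 145 and 16 in IL4/STAT6-induced, 28 and 50 in glucocorticoid-induced, 71 and 19 in lipid metabolism, 59 and 36 in phagocytosis and 33 and 16 in circadian genes. The share of higher calls was 53.4%, against 37.3% with scaling by low-count peaks (6196 higher, 10404 lower), which moved the median of all peaks from -0.023 to -0.217. Without IL4 replicate 3 the lower calls fell from 7711 to 4766.

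Set against IL4 directly, Cort gave 6741 higher and 8201 lower peaks and Dex 7238 and 8736. Cd163 was higher with Cort than with IL4 by 4.29 ± 0.19 (adjusted p = 3.21e-07). Armc12 was higher by 4.74 ± 0.33 with Cort and 4.91 ± 0.33 with Dex, a site 638 kb from Arid1b (17:4354450-4356747) by 5.04 ± 0.35 and 5.11 ± 0.35, and the site between Trpm3 and Klf9 by 4.51 ± 0.41 and 5.04 ± 0.41. Peaks in Ang6 (14:44006695-44008245, -5.32 ± 0.46 and -4.98 ± 0.44), near Ang5 (14:43965041-43968724, -5.19 ± 0.37 and -5.17 ± 0.37) and in Mad1l1 (-4.56 ± 0.34 and -4.88 ± 0.34) were lower with either steroid than with IL4. With the block the counts were 11915 higher and 12265 lower for Cort and 12669 and 12892 for Dex. The higher share of 45.1% for Cort and 45.3% for Dex became 68.8% and 65.0% with scaling by low-count peaks, so the balance of the directions depended on the scaling. The median of all peaks moved with it from 0.0492 to 0.341 for Cort and from 0.0587 to 0.302 for Dex. Without IL4 replicate 3 the higher calls fell to 4179 for Cort and 4522 for Dex.

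Whether the steroids and IL4 changed the same H3K27ac peaks was asked next. Peaks higher with Cort, Dex and IL4 numbered 164 and lower peaks 147. The first set held Klf9 (3.84 ± 0.26 with Cort, 4.01 ± 0.26 with Dex, 2.39 ± 0.25 with IL4), Nfil3 (1.41 ± 0.18, 1.66 ± 0.18, 1.40 ± 0.18), the cell cycle kinase Wee1 (7:110113046-110118288, 1.45 ± 0.15, 1.69 ± 0.15, 1.63 ± 0.15), Gda (19:21376189-21378212, 2.57 ± 0.30, 3.14 ± 0.30, 3.35 ± 0.30) and Irf2 (8:46786673-46796266, 0.99 ± 0.10, 1.06 ± 0.10, 0.80 ± 0.10). The second held Prdm1 (10:44436551-44439253, -1.32 ± 0.20, -1.43 ± 0.20, -1.38 ± 0.20), Clic4 (4:135225349-135233155, -0.98 ± 0.11, -1.14 ± 0.11, -0.77 ± 0.11) and Amer2 (14:60427369-60428834, 39.2 kb away, -1.38 ± 0.20, -1.83 ± 0.20, -1.56 ± 0.20). Other peaks went opposite ways. Dex raised and IL4 lowered 189, including Tns1 (1:74006401-74009384, 2.13 ± 0.17 and -1.32 ± 0.18), Man2a1 (17:64719477-64724941, 2.49 ± 0.16 and -1.10 ± 0.16) and St3gal5 (6:72159841-72166132, 1.26 ± 0.19 and -1.38 ± 0.19), and Dex lowered and IL4 raised 95, including Lpl (-1.24 ± 0.16 and 1.09 ± 0.16) and Ubash3b (9:41048193-41053173, -0.81 ± 0.13 and 0.89 ± 0.13). These examples were chosen by smallest p after the sets were formed.

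Cort and IL4 changed 317 peaks in the same direction, 165 higher and 152 lower, where independent lists would share 103.8 and 28.97. Dex and IL4 shared 403 higher and 854 lower peaks, against 255.6 and 180.8. Peaks with opposite calls numbered 88 higher and 20 lower with Cort against IL4 (independent lists 90.66 and 33.17), and 189 and 95 with Dex (223.3 and 207). Of the peaks lower with Cort or Dex, 67.6% and 60.8% were also lower with IL4, and of the higher ones 23.4% and 23.2% were also higher. Scaling by low-count peaks gave 100 higher and 57 lower shared peaks for Cort and IL4 (independent lists 69.33 and 11.81) and 221 and 592 for Dex and IL4 (152.4 and 140.7), with 120 and 4, and 227 and 23, of opposite calls. Scaling by total count gave 114 higher and 223 lower, and 299 and 1125. Unchanged groups simulated 10 times against the same vehicle libraries shared 0 calls, which says nothing of lists of the real sizes, and no simulation was made with the block. The covariance of the log2 changes over all peaks was 0.156 for Cort and IL4 against 0.0863 in the simulation (r 0.322 against 0.488), and 0.183 for Dex and IL4 against 0.0869 (r 0.322 against 0.499). The 3 vehicle libraries are too few to be divided between the contrasts, so part of the excess may come from the shared controls. With the block the shared counts were 1397 higher and 2544 lower for Cort and IL4, and 1919 and 3905 for Dex and IL4. The count of 317 fell to 103 without vehicle replicate 2, 86 without vehicle replicate 3, 114 without Cort replicate 1 and 115 without Cort replicate 3. The H3K27ac peaks changed in the same direction by Dex and IL4 fell from 1257 to 522, 437, 527 (Dex replicate 1) and 472 (Dex replicate 3). Cort and Dex shared 702 higher and 212 lower peaks (independent lists 20.39 and 5.275, covariance 0.262 against 0.0866), or 3574 and 3358 with the block, 557 and 306 with total count and 667 and 64 with low-count peaks. Their 914 shared peaks fell to 398 without vehicle replicate 2, 327 without vehicle replicate 3, 434 without Cort replicate 1 and 470 without Cort replicate 3.

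**Figure D2:**
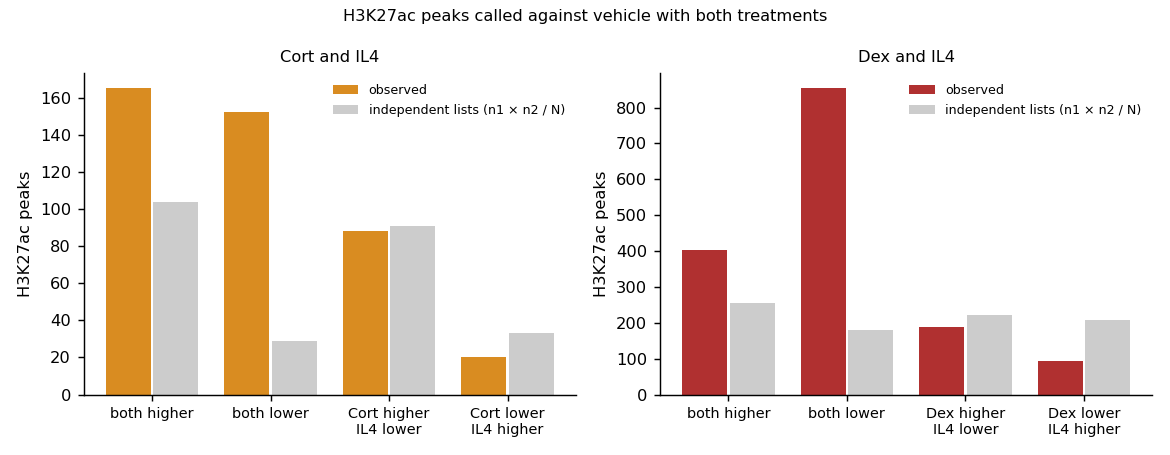
Number of H3K27ac peaks called against vehicle with both Cort and IL4 (left) and both Dex and IL4 (right), by pair of directions. Coloured bars are the observed counts and grey bars the number that independent lists of the same sizes would share. Both-lower peaks stood at 152 and 854 against 28.97 and 180.8.

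GR occupancy rose with both steroids near known target genes. Between Anapc16 and Ddit4 (10:59974098-59974448) the normalised CPM went from 4.30 ± 1.66 in vehicle to 94.2 ± 17.9 with Cort and 115 ± 32.1 with Dex (SD, n = 4 each). The log2 changes were 4.42 ± 0.41 and 4.71 ± 0.42 (adjusted p = 3.01e-05 and 1.47e-05). Near Tsc22d3 (X:140513382-140513747, 25.8 kb away) GR rose by 3.58 ± 0.42 with Cort and 3.62 ± 0.42 with Dex, in Zbtb16 (9:48723543-48724003) by 3.35 ± 0.35 and 3.67 ± 0.35, and in Fkbp5 (17:28420136-28420595) by 2.93 ± 0.34 and 3.24 ± 0.34. Vehicle near Tsc22d3 had 3.48 ± 3.37 normalised CPM (SD, n = 4). The median count per GR peak was 3 to 17 per library, so such folds rest on few vehicle reads. Other sites with high folds lay near Armc12 (17:28518000-28518382, 4.35 ± 0.55 and 4.29 ± 0.55), 61.4 kb from Trpm3 (19:23056835-23057211, 4.01 ± 0.40 and 4.27 ± 0.40), between Ergic1 and the phosphatase gene Dusp1 (17:26535142-26535626, 3.92 ± 0.35 and 3.94 ± 0.35), near Wee1 (7:110116890-110117284, 3.65 ± 0.39 and 3.63 ± 0.39) and, for Dex, near St3gal5 (6:72162105-72162494, 3.52 ± 0.30). The Armc12 site also lies within 50 kb of Fkbp5. At the sites named for their fold each steroid library lay above each vehicle library of its batch, as the rule required. In all, 662 peaks were higher and 769 lower with Cort, and 763 higher and 809 lower with Dex, with 607 higher and 644 lower with both. The shared counts were 1477 higher and 6 lower with total count, 190 and 3 with low-count peaks, and 638 and 283 without vehicle replicate 4. No peak differed between Dex and Cort at these unequal doses (0 of 5183 in edgeR, 468 at an unadjusted p under 0.05, 0 in DESeq2), and the median of all peaks went from -0.0142 to 0.171 with total count and 0.185 with low-count peaks. Over the 1251 peaks called with both, the slope of Dex on Cort was 1.09 and 72.3% of the 95% intervals of the difference lay within 1 log2 unit, and over all 5183 tested peaks the values were 0.678 and 37.8%.

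Of 17 glucocorticoid-induced genes with a tested GR peak, 13 rose and 1 fell with Cort, and 14 rose and 2 fell with Dex, among them Mertk (2:128746531-128746839, 2.62 ± 0.30 and 2.75 ± 0.30) and Hif3a (7:17058151-17058601, 2.82 ± 0.29 and 3.41 ± 0.30). Of the list's 40 peaks 25 were higher and 1 lower with Cort, the same adjusted over the list alone, and 26 and 2 with Dex, or 29 and 2 adjusted over the list alone (adjusted p = 4.56e-12 and 2.71e-14, and adjusted p = 0.00618 and 0.00364 with an estimated correlation). Circadian genes rose at 4 of 5 with each steroid, Per1 (11:69099265-69099591, 2.72 ± 0.36 and 2.82 ± 0.36), Per2 (1:91436344-91436658, 1.98 ± 0.32 and 2.48 ± 0.32), Nfil3 (13:52985467-52985792, 1.66 ± 0.39 and 2.02 ± 0.39) and Ciart (3:95882695-95882948, 2.01 ± 0.50 and 2.09 ± 0.50), with 6 and 7 higher and 0 lower peaks. Adjusted over the list alone 6 and 7 were higher and 0 and 1 lower (adjusted p = 0.000243 and 9.06e-05, and adjusted p = 0.0156 and 0.0117 with an estimated correlation). Among 10 regulators 5 rose with each, including Klf13 (7:63896854-63897283, 3.34 ± 0.34 and 3.49 ± 0.34), Klf9 (19:23134921-23135263, 3.33 ± 0.44 and 3.42 ± 0.44), Klf6 (13:5845671-5845890, 15.6 kb away, 2.23 ± 0.45 and 2.22 ± 0.45) and Fos (12:85464963-85465184, 2.07 ± 0.40 and 2.51 ± 0.40), with 9 higher peaks, 9 also adjusted over the list alone (adjusted p = 0.0008 and 0.000118, and adjusted p = 0.0156 and 0.0114 with an estimated correlation). F13a1 (13:37056667-37057104, 2.39 ± 0.26 and 2.53 ± 0.26) and Tgfbi (13:56616541-56616745, 1.24 ± 0.36 and 1.24 ± 0.35) rose in tissue remodelling, whose median of -0.518 with Cort differed in sign from its mean of 0.0283 (adjusted p = 0.73 and 0.346). Of 17 IL4/STAT6-induced genes 4 rose and Tfec (6:16923864-16924056, 25.4 kb away, -1.41 ± 0.44 and -1.41 ± 0.44) fell with each steroid. Rises included Pparg (6:115331042-115331288, 29.6 kb away, 1.47 ± 0.38 and 1.56 ± 0.38) and Il4ra (7:125561378-125561576, 1.16 ± 0.38 and 1.51 ± 0.38), with 4 higher and 1 lower peaks, or 1 and 0 with Cort and 3 and 1 with Dex adjusted over the list alone (adjusted p = 0.053 and 0.0581). This list tested up with total count (adjusted p = 0.0181 and 0.0273, with 15 and 18 higher and 0 lower peaks), and for Cort without Cort replicate 4 (adjusted p = 0.0248) and with the replicate block (adjusted p = 0.0446). Phagocytosis genes went both ways, with C1qb (4:136886112-136886506, 1.74 ± 0.33 and 1.94 ± 0.33) and C1qc (4:136892732-136893138, 1.96 ± 0.35 and 2.05 ± 0.35) of complement C1q rising (adjusted p = 0.754 and 0.803), and with Dex a median of -0.308 and a mean of -0.00165 against a test pointing up.

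Falls in GR were weaker and depended on how the counts were scaled. By the rule they included Hexa (9:59564852-59565092, -2.07 ± 0.47) and Them7 (2:105252931-105253093, -1.79 ± 0.30) with Cort, and Col4a6 (X:141276571-141276659, -2.69 ± 0.47), Lyst (13:13755015-13755151, -2.21 ± 0.38), Grk5 (19:60924659-60924784, -2.13 ± 0.53), Duxf3 (10:58231859-58232021, -2.12 ± 0.31) and Olfr1466 (19:13352348-13352446, -2.09 ± 0.47) with Dex. Duxf3 and Olfr1466 belong to multigene families where reads cannot be assigned with certainty. With scaling by total count 1556 peaks were higher and 24 lower with Cort, and 1954 higher and 25 lower with Dex. Those calls kept 662 of 662 and 763 of 763 higher peaks of the TMM fit, but 24 of 769 and 25 of 809 lower ones, whose median moved from -1.24 to -0.355 and from -1.35 to -0.263. The median of all peaks moved from 0.174 to 0.957 with Cort and from -0.124 to 0.859 with Dex, so falls are relative to the other peaks. Scaling by low-count peaks gave 190 higher and 11 lower with Cort and 496 and 46 with Dex (median of all peaks 0.157 with Dex), DESeq2 size factors moved the median with Cort to 0.0489, and no filter on low counts gave 599 and 154, and 871 and 339. Without vehicle replicate 4 the lower calls dropped from 769 to 332 with Cort and from 809 to 493 with Dex. Those with Cort fell to 485 without Cort replicate 3, and to 499 (686 higher) with the 1% of peaks with the most reads left out, an alternative chosen after the data were seen. Lists with lower GR must be read against this. With Cort the lipid metabolism (adjusted p = 0.00796), macrophage identity (adjusted p = 0.012) and interferon-response lists (adjusted p = 0.0186) tested down, and with Dex the lipid list (adjusted p = 0.0341). Called genes with Cort included Lpl (8:68895701-68895882, -1.72 ± 0.53), Cd14 (18:36725436-36725620, -2.01 ± 0.56) and Oasl1 (5:114922417-114922637, -1.01 ± 0.23). None held with an estimated correlation (adjusted p = 0.295, 0.331, 0.295 and 0.436). The interferon and Dex lipid calls ended without Cort replicate 4 (adjusted p = 0.0597 and 0.113). With total count the medians of the Cort lipid and macrophage lists turned from -0.843 to 0.0209 and from -0.766 to 0.11, and that of the Dex lipid list from -0.787 to 0.201, with the shift of all peaks. Against the other peaks the lists tested down with total count too (adjusted p = 0.00985 for Cort lipid, 0.0181 for macrophage identity, 0.0173 for interferon-response and 0.0273 for Dex lipid). That test sets a list against the other peaks, so a shift of all peaks alike hardly moves it. It therefore says little about the scaling. The lists also hold peaks that stood far higher in batch 1 than in batch 2, a set described below. A peak in Apoe of the lipid list (7:19696262-19697088) had 566 to 1370 counts in batch 1 and 3 to 19 in batch 2. Of the 104 peaks of that set, 14 were called lower with Cort, and 6 lower and 0 higher with Dex. How far that set accounts for the lists that tested down was not tested. Macrophage identity and interferon-response genes with Dex did not pass (adjusted p = 0.0541 and 0.21), nor did inflammatory and housekeeping genes with Cort (adjusted p = 0.744 and 0.294) or Dex (adjusted p = 0.901 and 0.346). The inflammatory median of -0.197 and mean of -0.12 with Dex lay below 0 while the test pointed up. Of the other cells' markers Xcr1 fell (9:123872963-123873133, -1.30 ± 0.31 and -1.39 ± 0.31), and S100a9 fell with Cort (3:90692639-90692833, -1.22 ± 0.41). Cd74, the 1 MHC class II gene measured, had 0.45 ± 0.38 and 0.61 ± 0.38 and did not pass.

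**Figure D3:**
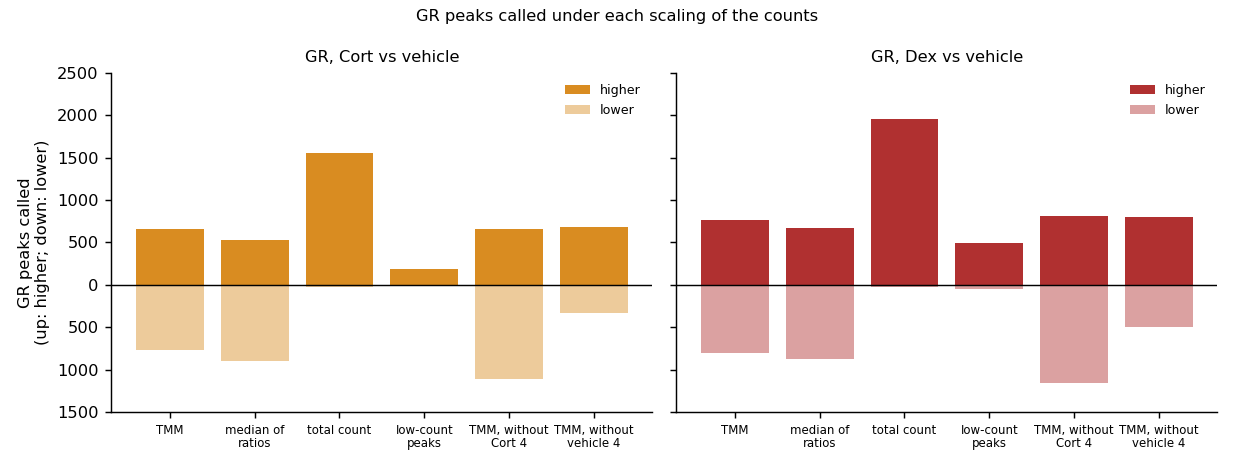
Number of GR peaks called higher (up) and lower (down) against vehicle for Cort (left) and Dex (right) with each scaling of the counts and without Cort replicate 4 or vehicle replicate 4. Higher calls stood at 662 and 763 with TMM, and lower calls at 769 and 809 with TMM but 24 and 25 with total count.

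In batch 1 alone GR was higher at 646 and lower at 535 peaks with Cort, and higher at 654 and lower at 573 with Dex. In batch 2 alone edgeR called 0 peaks for either (1465 and 1210 at an unadjusted p under 0.05). The signs in batch 2 of peaks called in batch 1 alone were counted after the data were seen. Of the higher peaks that batch 2 could test, 611 of 640 with Cort (95.5%, median 1.17) and 632 of 645 with Dex (98%, median 1.49) lay above 0 in batch 2, against 59.3% and 60.4% of all peaks tested in both. Of the lower ones 269 of 351 (76.6%) and 479 of 488 (98.2%) lay below 0, against 40.7% and 39.6%. Cort replicate 4 of batch 2 stood apart from the other libraries. With it left out, batch 2 alone called 433 higher and 477 lower peaks with Dex. Batch 2 then holds 1 Cort library, so no conclusion is drawn from its calls with Cort (median log2 change of all peaks -0.0436). In both batches together, without Cort replicate 4, Cort gave 656 higher and 1107 lower and Dex 808 and 1155. The 1251 peaks shared by Cort and Dex compared with 97.45 higher and 120 lower from independent lists, and the covariance was 0.847 against 0.21 in simulations of unchanged groups. With the vehicle libraries divided between the contrasts, the shared calls were 293 higher and 31 lower (independent lists 40.46 and 3.867, covariance 0.458) and 306 and 71 (45.15 and 10.01, covariance 0.615).

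The calls of GR occupancy with IL4 depended on the tool. EdgeR called 0 of 5183 (612 at an unadjusted p under 0.05), and DESeq2 called 25 higher and 166 lower. In batch 2 alone, which holds all IL4 libraries, edgeR called 0 (209 at an unadjusted p under 0.05). At Tsc22d3 the change was 1.41 ± 0.49 (adjusted p = 0.41), at Klf9 1.25 ± 0.50 (adjusted p = 0.41), at Per1 0.69 ± 0.41 (adjusted p = 0.522), at Pparg 1.31 ± 0.44 (adjusted p = 0.41) and at Runx1 (16:92620817-92621029) 1.48 ± 0.34 (adjusted p = 0.322). The glucocorticoid-induced and circadian lists tested up (adjusted p = 0.035 each, 0 peaks called, 0 adjusted over the list alone). Both calls ended with an estimated correlation (adjusted p = 0.154 each) and without Cort replicate 4 (adjusted p = 0.0609 each). The other tested lists ranged from adjusted p = 0.0996 to 0.79, and the medians of the inflammatory, phagocytosis and housekeeping lists (0.000829, 0.0385 and 0.0605) differed in sign from their means (-0.0591, -0.0433 and -0.0527). Scaling by total count moved the median of all peaks from -0.103 to 0.326 (0.179 with low-count peaks, -0.215 with DESeq2 size factors) and called 0 (663 at an unadjusted p under 0.05), and with Cort replicate 4 also left out 16 peaks were higher and 0 lower.

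The regions bound by GR were then set beside H3K27ac. Of 703 H3K27ac peaks over a GR peak higher with Dex, among them those at Klf9, Nfil3, Wee1, Tns1 and Man2a1, 390 (55.5%) rose with Dex and 0 fell, and 271 (38.5%) rose with Cort and 0 fell. Over no GR peak (n = 55976) 1.93% rose with Dex and 0.581% with Cort, odds ratios of 63.4 and 107. Over a GR peak that was not called (n = 2372) 9.57% rose with Dex and 3.96% with Cort (Fisher's exact test against no GR peak, two-sided, p = 1.87e-78 and 2.73e-42, across peaks, which are not independent replicates). IL4 raised 14.7% of the 703 peaks against 14.8% over no GR peak (Fisher's exact test, p = 0.957) and lowered 21.1% against 12.5% (p = 3.22e-10). Over an uncalled GR peak it raised 13.7% and lowered 18.7% (Fisher's exact test against no GR peak, p = 0.147 and 4.61e-17). In the other direction, 38.5% of the peaks higher with Cort and 22.5% of those higher with Dex lay over GR peaks higher with Dex, against 1.17% of all tested peaks, and 0 of the 225 and 1404 lower peaks did. Among the shared sets this share was 31.1% for peaks higher with Cort, Dex and IL4, 16.1% for the 403 higher with Dex and IL4, 38.1% for those higher with Dex and lower with IL4, 22.2% for those higher with Dex and not called with IL4, and 0 for each set lower with Dex. Of the GR peaks themselves, 97.5% of those higher with Dex, 77.6% of those not called and 14.5% of those lower lay over an H3K27ac peak.

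**Figure D4:**
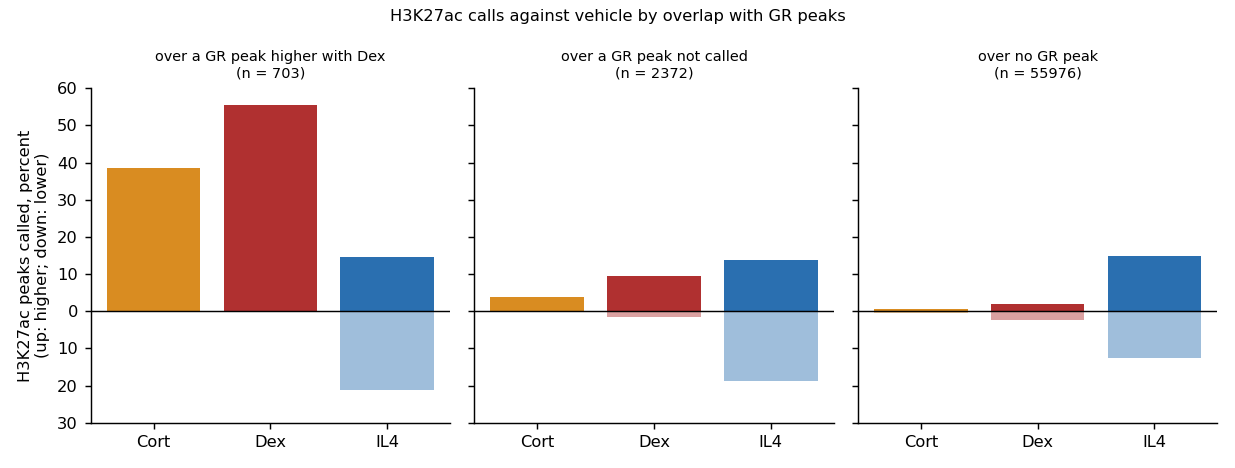
Percent of H3K27ac peaks called higher (up) and lower (down) against vehicle with Cort, Dex and IL4, for peaks over a GR peak higher with Dex (n = 703), over a GR peak not called (n = 2372) and over no GR peak (n = 55976). With Dex 55.5%, 9.57% and 1.93% were higher.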

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

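The tests of Cort replicates 1 to 3, of the correlation with IL4 replicate 1 and of the GR peaks lower with Dex were chosen after the result was seen. The remaining tests of Cort replicate 4 and of the batch 1 peaks were set after these patterns were seen, before each test was run. Library measures and the 31 named GR peaks were searched for samples far from the rest of their group, with a gap to the nearest library, as a share of the group's range, above Dixon's 95% critical value. This found 12 of 111 groups of 4 libraries (10.8%). The groups share libraries and scaling factors, and the peaks were named from these same data. The share therefore cannot be set against the 1 in 20 that independent groups would give by chance. H3K27ac groups of 3 were not searched.

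Cort replicate 4 of GR had 416169 counts outside the 1% of peaks with the most reads, against 113756 to 143618 in the other Cort libraries, and a mean Spearman correlation with its group of -0.0388 against 0.445 to 0.502. Its CPM between Anapc16 and Ddit4 was 121, against 84.7 to 85.7. Vehicle replicate 4 had a TMM factor of 0.392 (others 0.789 to 0.841). It also had the highest CPM at Ccser1 (49.1, others 5.57 to 10.8), Them7 (37.5, others 19.8 to 21), Speer4d (64.6, others 23.4 to 25.5), Col4a6 (81.4, others 13.4 to 24.8), Lyst (46.5, others 11.1 to 17) and Olfr1466 (93.1, others 25.5 to 36.2), all of them peaks named for a fall with a steroid. These CPM are TMM-normalised, so the low TMM factor raises every CPM of vehicle replicate 4. Its high values at these peaks are therefore not separate from that factor. Speer4d and Olfr1466 belong to families where reads cannot be assigned with certainty. Vehicle replicate 1 had a CPM of 8.49 at Tsc22d3 (others 1.29 to 2.23), and Dex replicate 4 had 1904442 counts in peaks (others 1185798 to 1289013).

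At 406 sites (7.83% of tested GR peaks) Cort replicate 4 stood more than 16 times above the mean of the Dex libraries, with 268196 counts there against 21210 in IL4 replicate 1, 11923 in vehicle replicate 3 and at most 8929 in any other library. A response to Cort that Dex does not share is argued against, since Cort replicates 1 to 3 lay below vehicle at these sites (median log2 ratio -0.385). Sites that respond to both steroids were left out when the sites were chosen against Dex, so a shared response could not be tested. A vehicle or IL4 library in its place is argued against by its gain at peaks higher with Dex. There its median log2 ratio to batch 2 vehicle was 1.84, and that of Cort replicate 3 was 1.83. Reads of another source mixed into several libraries may account for the sites, as their counts correlated with those of IL4 replicate 1 (Spearman 0.891), though those of the other libraries did so as well (0.578 to 0.849). Only 3 of the 406 sites were called with Cort.

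In the batch 1 GR libraries 104 peaks stood more than 16 times above batch 2. The genes with the highest level among them were these: Lyz2 had 2105 to 5166 counts in batch 1 and 8 to 30 in batch 2, Tmsb4x 726 to 1969 and 3 to 14, Apoe 566 to 1370 and 3 to 19, and Fth1 500 to 1319 and 6 to 14. Hormone-driven GR binding is argued against, since their median Dex change within batch 1 was 0.245 on the log2 scale (quartiles 0.149 and 0.374). Reads derived from RNA could not be told apart from other sources, because 86.5% of the peaks lay inside a gene (interval 78.4 to 92.4, other peaks 50.5%). This was short of the share set before the test was run, once the pattern had been seen. Recovery of active chromatin also stayed open, with 68.3% over an H3K27ac peak (58.4 to 77.1, other peaks 69.8%). Of these peaks 14 were called lower with Cort, 6 lower and 0 higher with Dex.

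Of the 809 GR peaks lower with Dex, 25 (3.09%) remained with scaling by total count. That scaling moved all GR peaks alike (median of all peaks from -0.124 to 0.859, of the lower calls from -1.35 to -0.263), so the loss of calls follows from the shift, and whether the scaling of the counts accounts for the falls stays open. Loss of GR from active regulatory regions is argued against, since 14.5% of them (12.1 to 17.1) lay over an H3K27ac peak against 77.6% of uncalled GR peaks.

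Other splits of the same libraries were counted in fits of the compared groups alone. For H3K27ac the 3 against 3 libraries give 10 splits, too few for a share under 0.05. As many calls as the real split came in 1 of 10 splits for Cort (real 385, highest other 0), Dex (1976 and 0), IL4 (18483 and 0), Cort against IL4 (13964 and 0) and Dex against IL4 (14927 and 0), and in 10 of 10 for Dex against Cort (0 and 0, edgeR, with 793 at an unadjusted p under 0.05 in the fit of all groups and 0 in DESeq2). Of the other splits 3 part all replicate pairs as the real one does, with 0 calls at most. For GR, 1 of 35 splits gave as many calls for Cort (real 1231, highest other 671) and 1 of 35 for Dex (1683 and 506), and the highest other split was the batches in each case. Of these, 18 keep 2 libraries of each batch on each side as the real one does, a count made after the result was seen (highest other 0 for both), too few for a share under 0.05. For IL4 35 of 35 splits gave as many as the real 0 (edgeR, with 612 at an unadjusted p under 0.05 in the fit of all groups and 191 in DESeq2; highest 430, with vehicle 1, 2 and 4 on a side), and for Dex against Cort 35 of 35 gave as many as the real 0 (468 unadjusted, 0 in DESeq2; highest 934, the batches). Every split gives at least 0 calls, so these counts say nothing of chance, and the calls of the other splits point to a structure of the samples apart from the treatments.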

How the results depend on the processing

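The settings that leave Cort replicate 4 out of every comparison, alone or with total count or batch 2 alone, were chosen after the result was seen. Named calls were counted once per peak and comparison, so a peak called with several treatments counts several times. All 198 named H3K27ac calls kept their sign, and 141 stayed called, in every alternative that tested them. Of 108 named GR calls 107 kept their sign and 0 stayed called in this way, where batch 2 alone, which called none, tested 88. The exception was Lyz2 (10:117277317-117278177), lower with Dex by -1.03 and reversed with total count (0.017) and with Cort replicate 4 out and total count (0.082). The cause was not tested for any change below, and the motif test was not run.

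With DESeq2 the calls were 1912 for H3K27ac Cort, 191 for GR IL4, 723 shared by Cort and IL4 and 1849 shared by Cort and Dex. With |log2 change| of at least 1 they were 613 (Cort), 1979 (Dex), 154 (Cort and IL4), 691 (Dex and IL4) and 591 (Cort and Dex). With the compared groups alone they were 385, 1976, 102, 837 and 383 in that order. With the replicate block H3K27ac gave 7531 (Cort), 12131 (Dex), 26057 (IL4), 24180 (Cort against IL4), 25561 (Dex against IL4), and 3941, 5824 and 6932 shared by Cort and IL4, Dex and IL4, and Cort and Dex. Scaling by low-count peaks gave 201 (Cort), 542 (Dex) and 193 (shared) for GR, and 157 and 813 H3K27ac peaks shared with IL4 by Cort and Dex. No count filter gave 753 (Cort) and 713 (shared) for GR. Batch 2 alone gave 0 for Cort, 0 for Dex and 0 shared, and without Cort replicate 4 it gave 66, 910 and 66, with 1 for Dex against Cort. Batch 2 without Cort replicate 4 holds 1 Cort library. Its counts for Cort, for shared peaks and for Dex against Cort therefore rest on a group without replicates, and no conclusion is drawn from them. Cort replicate 4 out with total count gave 16 for GR IL4. Divided vehicle libraries gave 324 and 377 GR peaks shared by Cort and Dex, or 450 and 752 without Cort replicate 4. Of 23 called lists in both assays 11 stayed called with camera's estimated correlation and 8 with peaks within 1 kb of a gene end. For GR alone 12 became 6 and 0. A list with fewer than 5 peaks near gene ends was not tested there, so that setting cannot tell lost calls from too few peaks.

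Leaving out each library of the groups compared gave H3K27ac ranges of 328 to 1073 (Cort), 1185 to 4168 (Dex), 11294 to 14712 (IL4), 10236 to 12834 (Cort against IL4), 11054 to 14857 (Dex against IL4), 86 to 432 (shared by Cort and IL4), 437 to 1589 (Dex and IL4) and 327 to 945 (Cort and Dex). Vehicle replicate 3 gave the lowest for Cort, Dex and the shared counts. GR ranges were 1011 to 1763 (Cort), 1270 to 1592 (Dex) and 921 to 1255 (shared). With Cort replicate 4 out of every fit the counts were 1963 (Dex) and 1483 (shared). Each left-out library gave 0 for GR IL4 and for Dex against Cort in both assays. The share of H3K27ac peaks over GR peaks that rose with Dex ranged from 40.3% to 56.3%.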

Other observations

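Among peaks not described above, IL4 raised H3K27ac near Acp5 (9:22143761-22145009, 0.86 ± 0.22), which encodes an acid phosphatase of osteoclasts and macrophages, and in Marchf10 (11:105438792-105440753, 4.61 ± 0.48), and lowered it near Nhsl2 (X:102093221-102095323, -3.45 ± 0.68) and near Sel1l (12:91801588-91805460, -3.33 ± 0.79). Dex lowered the peak 48.8 kb from Ifng that IL4 also lowered (10:118494690-118496413, -2.14 ± 0.44 with Dex). It also lowered peaks in Dscam (16:96633928-96635515, -2.25 ± 0.51) and Nme8 (13:19660997-19662698, -2.28 ± 0.45), and raised peaks near Ube2s (7:4816157-4817662, 4.42 ± 0.51) and Drap1 (19:5413247-5415955, 4.01 ± 0.38).

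Of all tested H3K27ac peaks 19.5% lay within 1 kb of a gene end, against 14.4% of those higher and 6.55% of those lower with Dex, 13.8% and 7.11% with Cort, and 13.2% and 11% with IL4. Called peaks were also longer (median 1870.5 bp higher and 1713 bp lower with Dex, 1091 bp tested), and these differences were not tested. GR peaks higher with Cort or Dex lay beyond 50 kb of a gene in 14.7% and 15.6%, and lower ones in 42.8% and 48.3%.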
